A study of Mus musculus with 15 samples.

How the data were processed

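Total RNA of a dendritic cell line, derived from the epidermis of newborn A/J mice per the labels, was measured on 15 mouse expression arrays, 3 in each of 5 groups (non-treated, DNFB, H2O2, DPI, and DPI + DNFB). Per the labels' protocols, RNA was extracted with TRIzol and an RNeasy Plus kit, and biotinylated cRNA was prepared with the 3' IVT Express kit. Per the submitters' processing notes, the values were made with MAS5 in Affymetrix Expression Console, with no versions given. The deposited values are intensity, a linear signal per probe set with no missing or negative values. Doses, exposure times and the time of harvest are not given. The number of arrays limits the precision, and no depth applies to this assay.

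The table held 45101 probe sets. Of these, 64 were array controls and were left out of the tests. Of the other 45037, 34945 were assigned to 1 gene symbol, 932 to several and 9160 to none. Symbols were taken from the platform's annotation and updated through gene identifiers in a reference gene table, used only for names, which matched 34741 and left 204 unmatched.

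The 2% trimmed mean of the deposited values was 250 on 6 arrays (replicate 1 of each group and DNFB replicate 3) and 500 on the other 9. The plan had been to keep the scaling as deposited. Because the arrays carried those different targets, each array was instead rescaled to a trimmed mean of 500, a deviation chosen after the values were seen; the counts from the values as deposited are given with the alternatives. The rescaled signals were transformed to log2 after adding a pseudocount of 15, the 20th percentile of the deposited values, so folds of dim genes are drawn toward 1. Probe sets were kept if their mean log2 signal was at or above the 40th percentile (6.22), which left 27022 probe sets, and the probe set with the highest mean represented each gene, giving 12701 genes.

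Group means were fitted to all 15 arrays together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend), which left 10 residual degrees of freedom. The 7 pairwise comparisons and the interaction, the effect of DNFB with DPI minus its effect without DPI, were tested with Benjamini-Hochberg adjustment over genes within each comparison, at an adjusted p below 0.05. Fold changes are given with the SE of the fit. Group signals are geometric means of the rescaled signal plus the pseudocount, with the pseudocount then subtracted. Of 29 gene lists of pathways and cell type markers, the 26 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison. They were tested again with an estimated correlation and with fry, which asks whether a list's genes move one way without comparing them with other genes. Of 73 list calls, 19 held with an estimated correlation, and a list whose call ended under at least 3 of 21 other alternatives is named with that number.

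Named genes followed a rule: for each comparison the 8 largest rises and 8 largest falls among genes that passed and whose groups did not overlap, leaving out unnamed and predicted genes. Added to these were up to 4 members that passed from each list with at least 3 such members or a camera call, and 11 genes of the oxidant response and of maturation in 4 comparisons whatever their values. The lists, the rule, the tests and the first alternatives were chosen before the data were examined. Of 706 named pairs of gene and comparison, 351 had more than 1 kept probe set, 39 passed while another probe set of the gene had the opposite sign, and in 3 the other probe set passed as well.

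The correlation and covariance of responses that share the non-treated arrays were set against 100 simulations of unchanged groups. The steps were tested on simulated data made from the scale of these arrays: of seeded changes of 0.5, 1 and 2 on the log2 scale, 24%, 55% and 88% were recovered, 8.3% of the calls were false, above the nominal 5%, and a comparison without seeded changes gave 0 calls. This was a single simulated set, and its shares vary with the random draw. The changes were seeded in 50, 100 and 50 of 12701 genes, far fewer than passed in the real comparisons, so the shares need not apply there. A list with a seeded shift had a camera p of 2.55e-16 and an unchanged list 0.538. Genes were simulated independently of each other, which those of a real list need not be.

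Alternatives covered the pseudocount, the signal filter, quantile, cyclic loess and median normalization, all probe sets or their mean per gene, the variance model, array weights, the replicate number as a block, only the groups compared, stricter thresholds and each array left out in turn. Added after the data were seen were the values as deposited, the scaling target as a block, each set of arrays with 1 target, DPI + DNFB replicate 2 as the only array of its group, and the beta-actin 3'/5' ratio as a covariate. The 3'/5' ratios were computed from the control probe sets of the deposited table.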

Results

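RNA from a dendritic cell line derived from mouse epidermis was measured on 15 oligonucleotide arrays, 3 in each of 5 groups. The cells were left non-treated, or received dinitrofluorobenzene (DNFB, a contact allergen that reacts with proteins), hydrogen peroxide (H2O2, an oxidant), diphenyl iodonium (DPI, an inhibitor of NADPH oxidase and other flavoenzymes that blocks the formation of reactive oxygen species), or DPI together with DNFB. The sample labels call the controls non-treated, while the description of the series speaks of vehicle, so it is open whether the controls received a solvent. The array held 45037 probe sets besides its controls, and 12701 genes were tested. Replicate arrays of a group correlated with r between 0.946 and 0.973 across genes, which are not independent replicates, and no pair of arrays held identical values. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision, with a median standard error of 0.197 on the log2 scale for a difference between groups.

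Control transcripts differed on the DPI + DNFB arrays, a group singled out after the ratios were seen. The ratio of signal at the 3' end to signal at the 5' end of beta-actin, which rises when RNA is degraded or incompletely copied, was 1.95 ± 0.405 (SD, n = 3) on the DPI + DNFB arrays and 1.25 ± 0.003 (SD, n = 3) on the non-treated arrays. The DPI + DNFB arrays had ratios of 2.07, 1.50 and 2.29, and the highest value among the other 12 arrays was 1.53. For Gapdh the ratio was 1.10 ± 0.16 (SD, n = 3) with DPI + DNFB and 0.849 ± 0.025 (SD, n = 3) without treatment, with 0.922 as the highest value among the other 12 arrays. RNA integrity itself was not measured, and degradation cannot be separated from incomplete copying here.

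**Figure D1:**
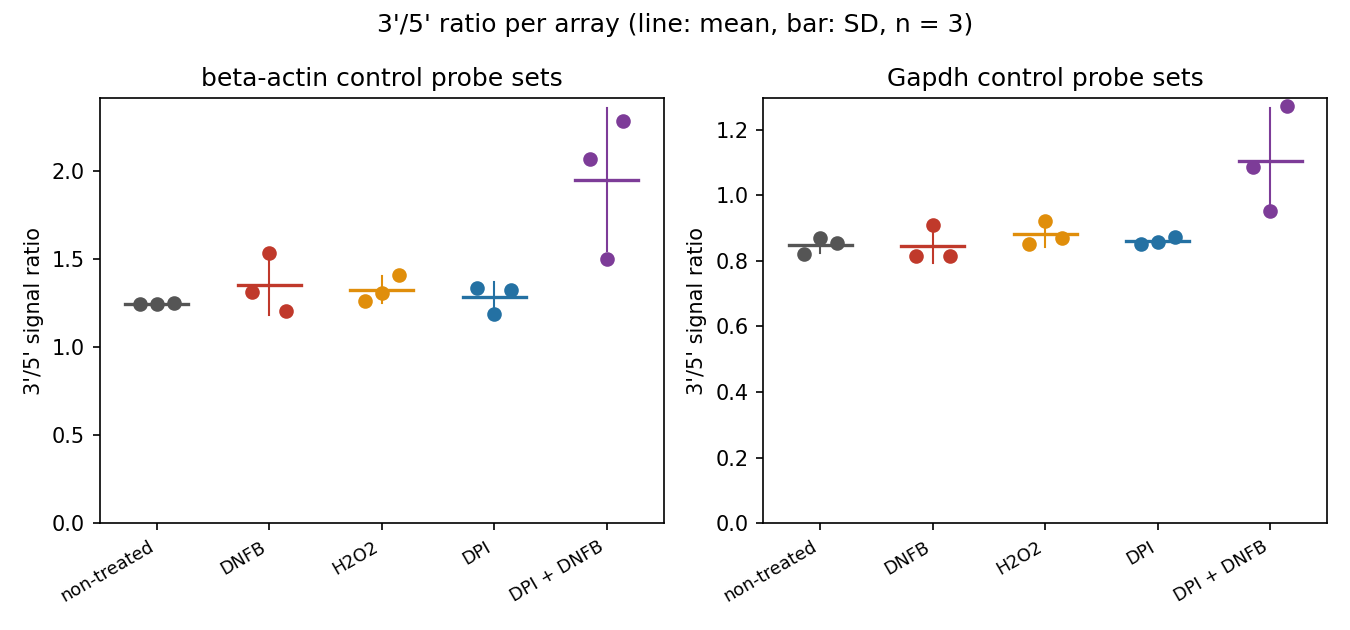
Ratio of 3' to 5' signal (vertical axis, no unit) of the beta-actin and Gapdh control probe sets on each array, by group, with points for arrays, lines for means and bars for SDs (n = 3). The DPI + DNFB arrays had a mean beta-actin ratio of 1.95, against 1.25 for non-treated arrays, and DPI + DNFB replicate 2, at 1.50, lay within the range of the other groups. For Gapdh that array, at 0.952, lay above the highest of the other 12 arrays, 0.922.

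DNFB against no treatment shows what the allergen did by itself. Some genes of the oxidant and electrophile response rose steeply: the heme-degrading enzyme Hmox1 rose 10.04-fold (log2 3.33 ± 0.276 SE, n = 3 arrays a group, limma adjusted p = 3.31e-08), from a mean signal of 1113 to 11310. Sulfiredoxin, Srxn1, rose 9.001-fold (log2 3.17 ± 0.129, adjusted p = 1.29e-12). The proteases Mmp12 and Mmp10 rose 26.4-fold and 19.95-fold, the neutrophil chemokine Cxcl3 22.9-fold and the chaperone Hspa1b 23.6-fold. The genes with the largest falls included the transcription factor Myb, which fell from a mean signal of 212.8 to 9.08, under the pseudocount of 15, so that its fold depends on the pseudocount. Others were Tmem119 (7.20-fold lower), Tifab (6.76-fold lower) and the potassium channel subunit Kcne3 (6.21-fold lower). All of the measured mitosis genes fell.

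Of 25 measured NRF2 and glutathione genes, 14 rose, 3 fell and 8 did not pass the test (15 rose and 3 fell when adjusted over the list alone). The list shifted up by 0.804 on the log2 scale relative to all genes (camera adjusted p = 7.31e-07; adjusted p = 0.00192 with an estimated correlation). Besides Hmox1 and Srxn1, the selective autophagy receptor Sqstm1 rose 4.95-fold, the cystine transporter Slc7a11 3.82-fold, the glutathione synthesis subunit Gclm 2.16-fold and the thioredoxin reductase Txnrd1 2.25-fold. The quinone reductase Nqo1 had a log2 fold change of 1.04 ± 0.55 that did not pass (adjusted p = 0.193). Among 14 other antioxidant enzymes 2 rose and 3 fell (adjusted over the list alone, 2 and 3), with glutaredoxin Glrx 3.86-fold higher and Sesn1 2.33-fold lower. The list was not called (camera adjusted p = 0.913, median log2 fold change -0.002 and mean 0.04). No NADPH oxidase gene passed the test over all genes, of 7 measured; adjusted over the list alone 2 fell. Cybb, the catalytic subunit of the phagocyte oxidase, had a log2 fold change of 0.001 ± 0.527.

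The cytokine, chemokine and NF-kB list had 16 of 30 genes up and 2 down (adjusted over the list alone, 17 and 2), with a shift of 1.10 (camera adjusted p = 4.09e-08; adjusted p = 0.00148 with an estimated correlation). Il23a rose 10.8-fold, Cxcl2 9.47-fold, Cxcl10 5.66-fold and Il1b 3.76-fold. In the dendritic cell maturation and antigen presentation list 9 of 26 genes rose and 5 fell (adjusted over the list alone, 9 and 5). The list as a whole was not called (camera adjusted p = 0.145). The costimulatory ligand Cd80 rose 5.96-fold and the maturation marker Cd83 5.41-fold, while Cd40 rose 1.62-fold and Cd86 1.48-fold (adjusted p = 0.0127). The call of Cd86 ended without non-treated replicate 1 or without DNFB replicate 2, at a log2 fold change of 0.44 in each case.

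Immediate early genes rose in 16 of 26 cases and fell in 2 (adjusted over the list alone, 18 and 3), led by the MAP kinase phosphatases Dusp1 (15.3-fold), Dusp4 (4.56-fold) and Dusp5 (4.46-fold). Their camera adjusted p of 1.29e-07 became adjusted p = 0.129 with an estimated correlation. The ATF4 and amino acid response list had 17 of 26 genes up and 3 down (adjusted over the list alone, 17 and 3), including Atf3 (6.10-fold) and Cebpb (4.45-fold). The camera adjusted p of this list was 4.66e-08, and adjusted p = 0.0583 with an estimated correlation. Of 19 heat shock genes 6 rose and none fell (adjusted over the list alone, 8 rose; camera adjusted p = 0.00272, adjusted p = 0.399 with an estimated correlation). Among them were Hspa1b, its near-identical copy Hspa1a (5.01-fold, from a mean signal of 6.13 that lies under the pseudocount) and Hsph1 (3.25-fold). Without DNFB replicate 1 the log2 fold changes of Hspa1b and Hspa1a were 5.46 and 2.97, against 4.56 and 2.32 with it. Of 19 p53 targets 8 rose and 2 fell (adjusted over the list alone, 8 and 2; camera adjusted p = 0.0212, adjusted p = 0.078 with an estimated correlation). Largest were the rises of Plk2 (6.41-fold; log2 2.05 without non-treated replicate 3) and the cell cycle inhibitor Cdkn1a (5.99-fold). Of 25 lysosome and autophagy genes 8 rose and none fell (adjusted over the list alone, 9 and 1; camera adjusted p = 0.00456, adjusted p = 0.078 with an estimated correlation). The lysosomal galactosidase Gla was 2.86-fold and the autophagy gene Gabarapl1 2.67-fold higher.

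Cell cycle genes fell with DNFB. Each of the 23 measured mitosis genes fell (23 adjusted over the list alone as well), with a shift of -1.05 (camera adjusted p = 7.51e-17; adjusted p = 0.00192 with an estimated correlation). Examples are Top2a (log2 -1.65 ± 0.152) and Aurkb (log2 -1.60 ± 0.226). Of 25 DNA replication genes 20 fell and none rose (adjusted over the list alone, 20; camera adjusted p = 1.15e-11, adjusted p = 0.00874 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 fell from a mean signal of 4532 to 986. The interferon response list had 11 of 25 genes down and none up (adjusted over the list alone, 11 and 1), including Usp18 (log2 -1.96 ± 0.209) and Ifit2 (log2 -1.86 ± 0.353). Its camera adjusted p of 0.00388 became adjusted p = 0.584 with an estimated correlation. Of 22 ribosome biogenesis genes 8 fell and none rose (adjusted over the list alone, 11 fell; camera adjusted p = 0.00072, adjusted p = 0.185 with an estimated correlation). Of 26 respiratory chain genes 7 fell and none rose (adjusted over the list alone, 9 fell; camera adjusted p = 0.00564, adjusted p = 0.401 with an estimated correlation). In all, 1337 genes rose and 1768 fell among the 12701 tested, and 403 and 476 of these changed at least 2-fold. With the scaling target of the arrays as a block 3320 genes passed, against 1349 within the arrays scaled to 500 and 2124 within those scaled to 250. The arrays scaled to 500 hold 1 DNFB array, and those scaled to 250 hold 1 array of each group other than DNFB, so a group of 1 array takes its spread from the other groups.

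**Figure D2:**
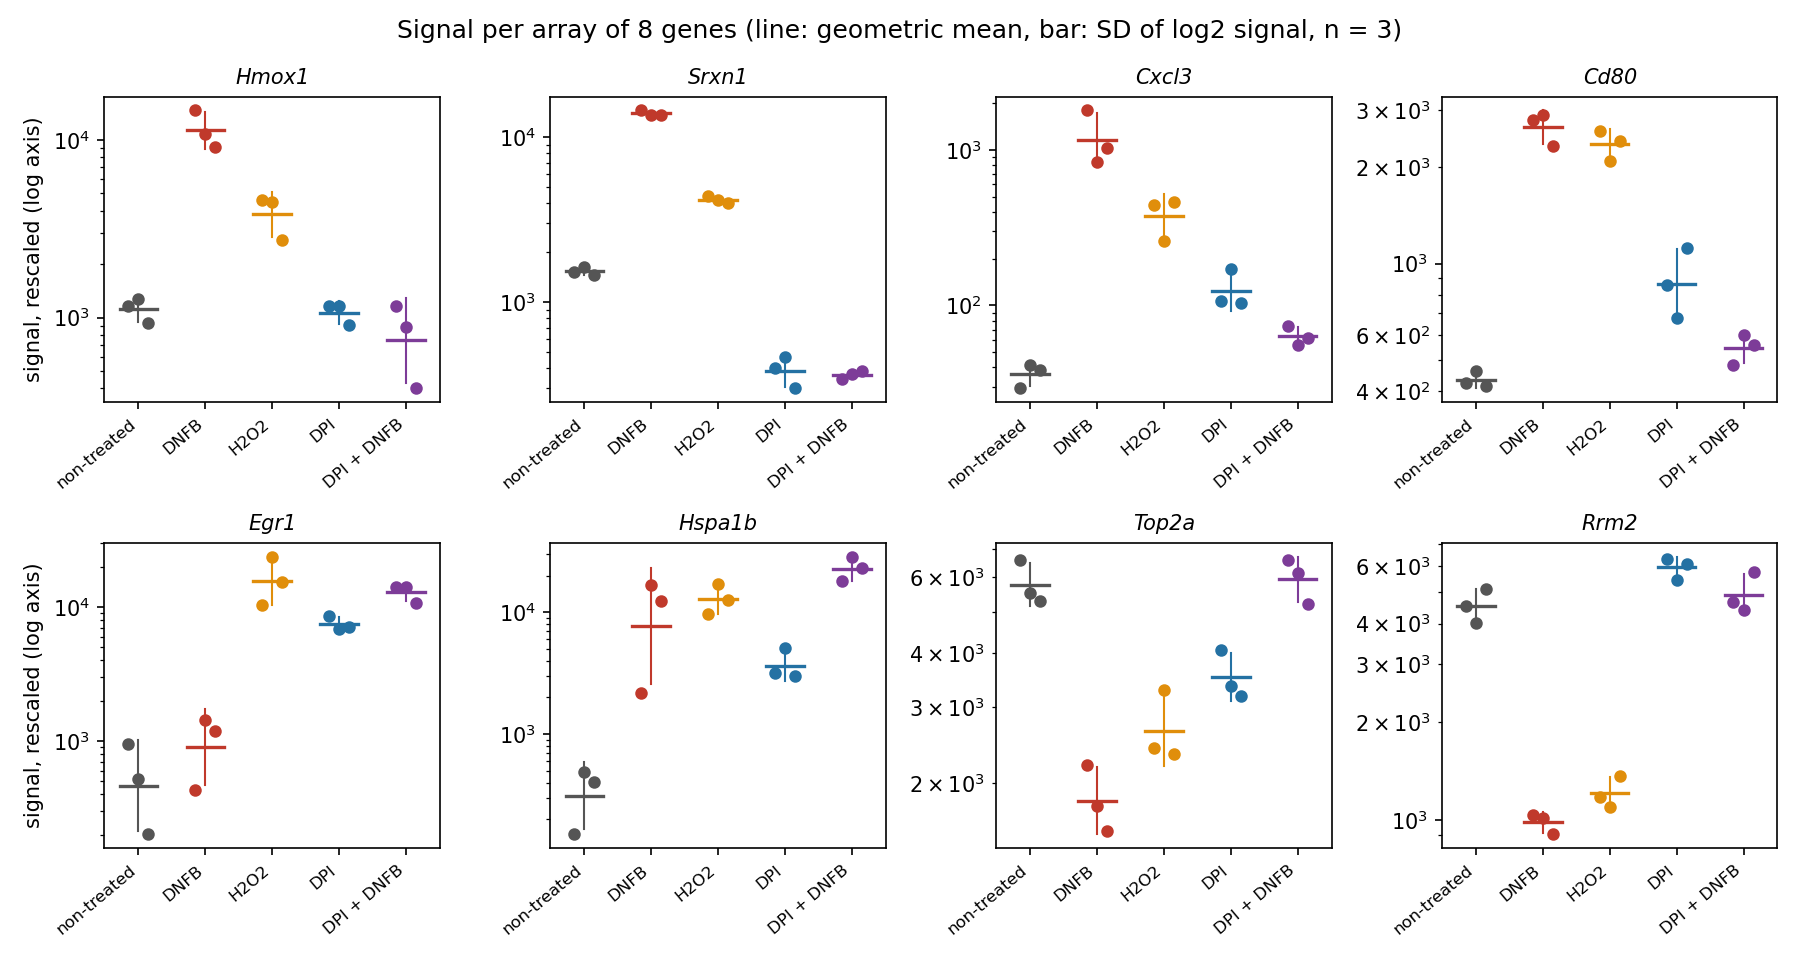
Rescaled signal (vertical log axes, arbitrary units) on each array for 8 genes, by group; points are arrays, lines geometric means and bars the SD of the log2 signal (n = 3). Lines and bars were drawn without the pseudocount, which the mean signals given here involve. Hmox1 and Srxn1 had mean signals of 11310 and 13940 with DNFB and of 747.1 and 363.2 with DPI + DNFB. Rrm2 had 986 with DNFB and 4905 with DPI + DNFB.

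H2O2 against no treatment shows the response to an added oxidant. The immediate early transcription factor Egr1 rose 32.4-fold (log2 5.02 ± 0.419 SE, n = 3 arrays a group, adjusted p = 3.66e-08), Hspa1b 39.0-fold, the chemokine Ccl3 24.6-fold and the maturation marker Cd83 14.2-fold. Hmox1 rose 3.41-fold and Srxn1 2.70-fold. The largest falls were of Tifab (log2 -3.04 ± 0.415; -2.45 without H2O2 replicate 1), Abhd15 (log2 -2.86 ± 0.204) and Cd7 (log2 -2.80 ± 0.506). All 23 measured mitosis genes fell.

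Of 26 immediate early genes 20 rose and 1 fell (adjusted over the list alone, 21 and 1), with a shift of 1.67 (camera adjusted p = 2.73e-16; adjusted p = 0.0239 with an estimated correlation). Gadd45b rose 12.2-fold and Fosb 7.17-fold. In the cytokine, chemokine and NF-kB list 18 of 30 genes rose and none fell (adjusted over the list alone, 21; camera adjusted p = 1.99e-12, adjusted p = 0.000214 with an estimated correlation), with Cxcl2 10.8-fold and Il23a 9.70-fold higher. The dendritic cell maturation list had 10 of 26 genes up and none down (adjusted over the list alone, 12 and 2), including Cd80 (5.27-fold), the adhesion molecule Icam1 (4.16-fold) and Cd40 (2.92-fold). Its camera adjusted p of 0.00033 became adjusted p = 0.125 with an estimated correlation. Cd86 had a log2 fold change of -0.02 ± 0.16 (adjusted p = 0.932).

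The ATF4 list had 18 of 26 genes up and 1 down (adjusted over the list alone, 20 and 1; camera adjusted p = 8.29e-11, adjusted p = 0.0239 with an estimated correlation), led by Atf3 (13.8-fold) and Nupr1 (4.48-fold). Of 19 heat shock genes 9 rose and none fell (adjusted over the list alone, 10; camera adjusted p = 6.2e-05, adjusted p = 0.239 with an estimated correlation), including Dnajb1 (2.79-fold) and Bag3 (2.50-fold). NRF2 and glutathione genes rose in 8 of 25 cases and fell in 2 (adjusted over the list alone, 8 and 2; camera adjusted p = 0.0152, adjusted p = 0.0481 with an estimated correlation). This call ended under 3 of 21 alternatives, quantile and cyclic loess normalization among them. Sqstm1 rose 4.74-fold, whereas Gclm (log2 0.16 ± 0.144, adjusted p = 0.458) and Nqo1 (log2 0.04 ± 0.55, adjusted p = 0.97) did not pass. Lysosome and autophagy genes rose in 7 of 25 cases with none down (adjusted over the list alone, 7; camera adjusted p = 0.0131, adjusted p = 0.114 with an estimated correlation), and their call also ended under 3 of 21 alternatives.

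The mitosis list shifted by -1.04 (camera adjusted p = 2.16e-15; adjusted p = 0.00443 with an estimated correlation), with 23 of 23 down over the list alone too, and Cenpf fell by 1.66 on the log2 scale. Of 25 DNA replication genes 19 fell and none rose (adjusted over the list alone, 20; camera adjusted p = 1.2e-09, adjusted p = 0.0239 with an estimated correlation). Of 19 p53 targets 7 rose and 6 fell (adjusted over the list alone, 8 and 6; camera adjusted p = 0.546). Cdkn1a rose 6.87-fold and the death receptor Fas 6.43-fold, while Trp53inp1 was at a log2 fold change of -2.32 ± 0.209. In all, 1380 genes rose and 2211 fell, 362 and 609 of them at least 2-fold, whereas the values as deposited gave 102 up and 74 down. With the scaling target as a block 3805 genes passed, against 2470 within the arrays scaled to 500 and 1784 within those scaled to 250.

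The responses to DNFB and to H2O2 had many genes in common, and 1941 genes passed in both with the same direction, 789 up and 1152 down, while 36 passed in opposite directions. Both comparisons use the same 3 non-treated arrays. Independent lists of these sizes would share 453. The fold changes correlated across genes, which are not independent replicates, with r = 0.692. In 100 simulations of unchanged groups against those controls r was 0.499. With many genes changed, that value is no reference for the real r. The covariance of the fold changes was 0.251 against a simulated 0.0492, a difference of 0.202. Part of the overlap may come from the shared controls, which at 3 arrays cannot be split into parts of at least 2. Within the arrays scaled to 500 the overlap was 865 and within those scaled to 250 it was 1031, against 2070 with the scaling target as a block.

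DNFB against H2O2 compares the allergen and the oxidant directly, at doses and times that are not given. Dose and timing therefore cannot be told apart from the compound. NRF2 and glutathione genes were higher with DNFB: 10 of 25 passed as higher and none as lower (adjusted over the list alone, 10 and 1; camera adjusted p = 0.00035, adjusted p = 0.0327 with an estimated correlation). Srxn1 was 3.34-fold, Blvrb 2.98-fold and Hmox1 2.94-fold higher. Ribosome biogenesis genes were lower with DNFB, with 11 of 22 lower and none higher (adjusted over the list alone, 15 lower), a shift of -0.554 (camera adjusted p = 3.91e-10; adjusted p = 0.0473 with an estimated correlation). Members included Nip7 (log2 -0.88 ± 0.173) and Rrs1 (log2 -0.85 ± 0.14). Egr1 was 17.0-fold lower with DNFB (log2 -4.08 ± 0.419 SE, n = 3 arrays a group, adjusted p = 2.29e-06). The largest folds of DNFB over H2O2 were those of the mucin Muc3 (7.90-fold), C1qtnf6 (7.16-fold) and the protein C receptor Procr (5.96-fold). For C1qtnf6 the gap came mostly from a low signal with H2O2, 39.8, against 377.6 with DNFB and 275.1 without treatment.

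Of 26 immediate early genes 14 were lower with DNFB than with H2O2 and 3 higher (adjusted over the list alone, 16 and 3; camera adjusted p = 7e-06, adjusted p = 0.328 with an estimated correlation), Gadd45b (4.55-fold lower) among them. Interferon response genes were lower in 8 of 25 cases and higher in none (adjusted over the list alone, 15 lower; camera adjusted p = 6.63e-07, adjusted p = 0.457 with an estimated correlation). In the maturation list 6 of 26 genes were lower and 2 higher (adjusted over the list alone, 10 and 2; camera adjusted p = 0.00035, adjusted p = 0.227 with an estimated correlation). Icam1 was 3.78-fold lower and Cd83 2.62-fold lower. The cytokine list had 7 of 30 genes lower and 4 higher (adjusted over the list alone, 8 and 4; camera adjusted p = 0.0358, adjusted p = 0.128 with an estimated correlation). Ccl3 was 4.47-fold lower and Cxcl3 2.99-fold higher. Respiratory chain genes were lower in 3 of 26 cases and higher in 1 (adjusted over the list alone, 7 and 1; camera adjusted p = 0.0049, adjusted p = 0.457 with an estimated correlation). That call ended under 4 of 21 alternatives. The mitosis list had 2 of 23 genes higher and 2 lower (adjusted over the list alone, 2 and 2; camera adjusted p = 0.987, with a mean of 0.02 and a shift of -0.009). In all, 1111 genes were higher with DNFB and 762 lower, 249 and 124 of them at least 2-fold. Centring each array on its median instead gave 985 higher and 407 lower. The values as deposited gave 4 higher and 22 lower, but their unequal targets moved the median of all genes by -0.311. With the scaling target as a block 2125 genes passed, against 353 within the arrays scaled to 500, which hold 1 DNFB array, and 719 within those scaled to 250.

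DPI against no treatment gives the effect of the inhibitor, the background on which DNFB acts in the combined group. The kinase gene Sgk1 rose 19.6-fold (log2 4.29 ± 0.232 SE, n = 3 arrays a group, adjusted p = 1.18e-10), and the immediate early genes Egr2, Egr1 and Fos rose 17.6-fold, 15.5-fold and 13.1-fold. Srxn1 fell by 1.96 on the log2 scale, from a mean signal of 1535 to 382.9. The long noncoding RNA Neat1 had the largest fall (log2 -4.45 ± 0.447), followed by Fam43a (log2 -3.87 ± 0.197) and the interleukin 10 receptor chain Il10ra (log2 -3.61 ± 0.365; -4.22 without DPI replicate 2).

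Of 26 immediate early genes 15 rose and 2 fell (adjusted over the list alone, 15 and 2; camera adjusted p = 3.92e-05, adjusted p = 0.309 with an estimated correlation). NRF2 and glutathione genes went both ways, with 5 of 25 up and 9 down (adjusted over the list alone, 7 and 11; camera adjusted p = 0.722). Ugdh rose 3.53-fold, whereas Osgin1 was at a log2 fold change of -1.75 ± 0.255 and Gclm at -1.21 ± 0.144. Of 14 antioxidant enzymes 4 rose and none fell (adjusted over the list alone, 4; camera adjusted p = 0.0749), led by Glrx (4.41-fold). Respiratory chain genes rose in 9 of 26 cases with none down (adjusted over the list alone, 14; camera adjusted p = 0.000464, adjusted p = 0.309 with an estimated correlation), for example the succinate dehydrogenase subunit Sdhc (1.42-fold). Of 18 hypoxia response genes 9 rose and 2 fell (adjusted over the list alone, 10 and 3; camera adjusted p = 0.00334, adjusted p = 0.331 with an estimated correlation). Ndrg1 rose 4.06-fold and Bhlhe40 was at a log2 fold change of -1.65 ± 0.208. Of 17 glycolysis genes 9 rose and 2 fell (adjusted over the list alone, 11 and 2; camera adjusted p = 0.0229, adjusted p = 0.543 with an estimated correlation), Slc2a3 rising 2.71-fold.

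Sterol synthesis genes rose in 7 of 19 cases with none down (adjusted over the list alone, 7; camera adjusted p = 0.0058, adjusted p = 0.331 with an estimated correlation), including Fdps (2.82-fold) and Idi1 (2.38-fold). Lysosome and autophagy genes rose in 13 of 25 cases and fell in 1 (adjusted over the list alone, 15 and 1; camera adjusted p = 0.003, adjusted p = 0.169 with an estimated correlation), the protease Ctsl by 3.36-fold. The ATF4 list had 14 of 26 genes up and 3 down (adjusted over the list alone, 14 and 5; camera adjusted p = 0.00096, adjusted p = 0.309 with an estimated correlation). The cytokine list had 12 of 30 up and 3 down (adjusted over the list alone, 12 and 3; camera adjusted p = 0.0211, adjusted p = 0.169 with an estimated correlation). Ccl3 rose 10.6-fold, Cxcl10 8.10-fold and Cxcl2 4.30-fold, while Tnf was at a log2 fold change of -1.77 ± 0.459, and at -1.02 without DPI replicate 1. Heat shock genes rose in 6 of 19 cases (adjusted over the list alone, 6; camera adjusted p = 0.0211, adjusted p = 0.543 with an estimated correlation). The p53 targets rose in 7 of 19 and fell in 2 (adjusted over the list alone, 7 and 2; camera adjusted p = 0.0241, adjusted p = 0.175 with an estimated correlation). Among 20 ER chaperone genes 5 rose and 1 fell (adjusted over the list alone, 5 and 1; camera adjusted p = 0.0466, adjusted p = 0.543 with an estimated correlation). Dnajb9 was 5.65-fold up and Xbp1 at a log2 fold change of -1.67 ± 0.168, and the call of the list ended under 10 of 21 alternatives. The glycolysis call ended under 4, and those of the heat shock and p53 lists under 3 each, quantile and cyclic loess normalization being among those that ended glycolysis and heat shock.

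Ribosome biogenesis genes fell in 10 of 22 cases with none up (adjusted over the list alone, 11; camera adjusted p = 0.003, adjusted p = 0.309 with an estimated correlation), for example Polr1b (log2 -1.54 ± 0.263) and Wdr12 (log2 -1.43 ± 0.16). Mitosis genes moved in both directions, with 5 of 23 up and 8 down (adjusted over the list alone, 6 and 8; camera adjusted p = 0.812). Aurka rose 1.99-fold and Top2a was at a log2 fold change of -0.71 ± 0.152. DNA replication genes rose in 12 of 25 cases and fell in 2 (adjusted over the list alone, 12 and 2; camera adjusted p = 0.0211, adjusted p = 0.331 with an estimated correlation), Ccne2 by 2.56-fold. In all, 1694 genes rose and 2341 fell, 425 and 755 of them at least 2-fold. With the scaling target as a block 4253 genes passed, against 2558 within the arrays scaled to 500 and 2326 within those scaled to 250.

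DPI + DNFB against DPI shows the effect of the allergen when the inhibitor is present. The NRF2 genes that led the response to DNFB alone did not pass as higher here. Hmox1 had a log2 fold change of -0.51 ± 0.276 (SE, n = 3 arrays a group, adjusted p = 0.181), Srxn1 -0.07 ± 0.129 (adjusted p = 0.719) and Slc7a11 0.56 ± 0.261 (adjusted p = 0.119), and Sqstm1 fell by 0.51 (adjusted p = 0.00355). Gclm (log2 -0.11 ± 0.144, adjusted p = 0.601) and Nqo1 (log2 -0.30 ± 0.55, adjusted p = 0.734) did not pass and Txnrd1 fell by 0.73 (adjusted p = 8.71e-05), whereas Osgin1 rose 2.70-fold (adjusted p = 0.000386). Some heat shock and ATF4 genes rose, with Hspa1b 6.24-fold, Bag3 2.89-fold, the stress transcription factor Ddit3 3.94-fold and Trib3 3.26-fold higher. The genes with the largest rises were the nucleoside diphosphate kinase Nme1 (7.35-fold) and the sperm membrane protein gene Spaca4 (6.93-fold), and the largest falls were of Abhd3 (log2 -2.40 ± 0.418) and Crisp3 (log2 -2.32 ± 0.212). The beta-actin 3'/5' ratio was 1.95 on the DPI + DNFB arrays against 1.28 on the DPI arrays. The groups compared thus differed in that ratio as well as in DNFB, which bears on each gene group here.

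ATF4 genes rose in 16 of 26 cases and fell in 1 (adjusted over the list alone, 17 and 1; camera adjusted p = 0.0017, adjusted p = 0.302 with an estimated correlation). Heat shock genes rose in 8 of 19 cases and fell in 1 (adjusted over the list alone, 10 and 1; camera adjusted p = 0.0355, adjusted p = 0.55 with an estimated correlation). Of 26 immediate early genes 12 rose and 1 fell (adjusted over the list alone, 14 and 2; camera adjusted p = 0.0246, adjusted p = 0.55 with an estimated correlation), Jun by 2.18-fold. In the cytokine list 12 of 30 genes rose and 2 fell (adjusted over the list alone, 14 and 3; camera adjusted p = 0.0315, adjusted p = 0.246 with an estimated correlation). Ccl4 was 2.37-fold, Cxcl2 2.25-fold and Il1b 2.02-fold higher and Cxcl10 at a log2 fold change of -1.42 ± 0.33. Ribosome biogenesis genes rose in 11 of 22 cases and fell in 1 (adjusted over the list alone, 11 and 3; camera adjusted p = 0.0246, adjusted p = 0.41 with an estimated correlation), Nop56 by 2.53-fold. ER chaperone genes fell in 6 of 20 cases with none up (adjusted over the list alone, 7 and 1; camera adjusted p = 0.0357, adjusted p = 0.55 with an estimated correlation), including Atf6 (log2 -1.15 ± 0.146) and Pdia3 (log2 -0.95 ± 0.205), a call that ended under 10 of 21 alternatives.

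Mitosis genes rose in 6 of 23 cases with none down (adjusted over the list alone, 6; camera adjusted p = 0.0497, adjusted p = 0.451 with an estimated correlation), among them Mki67 (1.97-fold) and Cdc20 (1.88-fold). Metal and iron handling genes fell in 7 of 14 cases and rose in 3 (adjusted over the list alone, 7 and 3), and p53 targets fell in 8 of 19 and rose in 3 (adjusted over the list alone, 9 and 4), both with a camera adjusted p of 0.0497 and adjusted p = 0.246 with an estimated correlation. The calls of the mitosis, metal and p53 lists ended under 11, 12 and 11 of 21 alternatives. Those of the heat shock and cytokine lists ended under 3 each, the beta-actin covariate among them. Of 25 NRF2 and glutathione genes 2 rose and 7 fell (adjusted over the list alone, 3 and 7; camera adjusted p = 0.108), Gclc at a log2 fold change of -1.61 ± 0.129. Cd80, which had risen with DNFB alone, was at a log2 fold change of -0.65 ± 0.158, although another of its 3 probe sets was at 0.20, and Cd86 at -0.13 ± 0.16 (adjusted p = 0.587). In all, 1785 genes rose and 1745 fell, 380 and 288 of them at least 2-fold, whereas with each array centred on its median 666 rose and 2863 fell, since that centring moved the median of all genes by -0.253. The calls of Spaca4, Hspa1b, Cxcl2, Cxcl10, Cdc20, Jun, Pdia3 and Cd80 ended with the beta-actin ratio as a covariate, and those of Spaca4, Il1b, Cxcl10, Pdia3 and Cd80 with DPI + DNFB replicate 2 alone. With the beta-actin ratio as a covariate 541 genes passed, with DPI + DNFB replicate 2 as the only array of its group 1270, and with the scaling target as a block 3782, against 2225 within the arrays scaled to 500 and 1438 within those scaled to 250.

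DPI + DNFB against DNFB shows how cells given the allergen differed when the inhibitor was added. NRF2 and glutathione genes were lower, with 16 of 25 down and 5 up (adjusted over the list alone, 17 and 5; shift -1.19, camera adjusted p = 2.86e-05, adjusted p = 0.00876 with an estimated correlation). Srxn1 was 36.9-fold lower (log2 -5.21 ± 0.129 SE, n = 3 arrays a group, adjusted p = 4.06e-16), Hmox1 14.9-fold, Gclm 5.40-fold and Txnrd1 4.50-fold lower. Mitosis genes were higher in 23 of 23 cases (23 adjusted over the list alone; shift 1.21, camera adjusted p = 1.39e-12, adjusted p = 0.00876 with an estimated correlation), such as Cdc20 (3.52-fold) and Top2a (3.24-fold). The signalling adaptor Traf1 had the largest fall (56.0-fold lower, with the pseudocount added), followed after Srxn1 by the immune checkpoint receptor Havcr2 (36.0-fold lower). The DPI + DNFB arrays had a mean beta-actin 3'/5' ratio of 1.95 and the DNFB arrays 1.35, which bears on every group of genes in this comparison.

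DNA replication genes were higher in 20 of 25 cases and lower in none (adjusted over the list alone, 20; camera adjusted p = 8.08e-09, adjusted p = 0.0301 with an estimated correlation), Rrm2 by 4.92-fold and cyclin E gene Ccne1 by 4.69-fold. Interferon response genes were higher in 19 of 25 cases with none lower (adjusted over the list alone, 19; camera adjusted p = 0.000164, adjusted p = 0.514 with an estimated correlation), including Oas1a (3.49-fold) and Usp18 (3.38-fold). Respiratory chain genes were higher in 14 of 26 cases and lower in 2 (adjusted over the list alone, 15 and 2; camera adjusted p = 0.00147, adjusted p = 0.389 with an estimated correlation). Glycolysis genes were higher in 10 of 17 and lower in 1 (adjusted over the list alone, 13 and 1; camera adjusted p = 0.00805, adjusted p = 0.514 with an estimated correlation), with Tpi1 2.66-fold higher. The glycolysis call ended under 3 of 21 alternatives.

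Inflammatory and maturation genes went in both directions. In the cytokine list 7 of 30 genes were higher and 8 lower (adjusted over the list alone, 7 and 8; camera adjusted p = 0.6, median log2 fold change 0.14 and mean -0.23). Cxcl3 was 14.97-fold and Il23a 8.04-fold lower, and Ccl2 was 4.09-fold higher. Cxcl2 (log2 0.03 ± 0.194, adjusted p = 0.913) and Il1b (log2 0.003 ± 0.227, adjusted p = 0.993) did not pass. Cd80 was 4.77-fold and Cd86 2.05-fold lower, within a maturation list of 26 genes with 8 higher and 8 lower (adjusted over the list alone, 8 and 8; camera adjusted p = 0.914, median 0.16 and mean -0.08). Cd40 was 1.32-fold lower, a call that ended without DNFB replicate 1 (log2 -0.36) and without DPI + DNFB replicate 1 or 2 (log2 -0.38 each). Immediate early genes were higher in 11 of 26 cases and lower in 10 (adjusted over the list alone, 11 and 10; camera adjusted p = 0.509), with Egr1 14.0-fold, Egr2 9.71-fold and Fos 9.42-fold higher. With DPI alone against no treatment Egr1, Egr2 and Fos had risen 15.5-fold, 17.6-fold and 13.1-fold. Langerin, Cd207, a Langerhans cell receptor, was 19.9-fold lower. Of 19 apoptosis regulators 4 were higher and 8 lower (adjusted over the list alone, 4 and 8; camera adjusted p = 0.127), among the latter the survival gene Mcl1 (3.42-fold lower). Mcl1 was also lower with DPI alone against no treatment (log2 -1.49 ± 0.198), with a mean signal of 4068 with DPI and 4230 with both compounds. In all, 2911 genes were higher and 2706 lower, 1117 and 966 of them at least 2-fold. Median centring gave 1617 higher and 3812 lower and moved the median of all genes by -0.274, so the balance depends on whether arrays are centred. The values as deposited gave 658 higher and 171 lower. They keep the unequal targets, with 2 DNFB arrays at 250, which moved that median by 0.31. The deposited balance thus carries the shift of the targets. With the beta-actin ratio as a covariate 2904 genes passed, with DPI + DNFB replicate 2 as the only array of its group 3652, and with the scaling target as a block 5849, against 3476 within the arrays scaled to 500 and 4701 within those scaled to 250.

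DPI + DNFB against no treatment gives the state of cells that received both compounds. Hspa1b rose 69.7-fold (log2 6.12 ± 0.511 SE, n = 3 arrays a group, adjusted p = 3.94e-08), Egr1 26.7-fold and Gadd45b 18.5-fold. Crtam rose from a mean signal of 7.19, under the pseudocount of 15, to 390.9. Srxn1 was 4.10-fold and Gclm 2.50-fold lower than in non-treated cells, in an NRF2 list with 4 of 25 genes up and 8 down (adjusted over the list alone, 5 and 9; camera adjusted p = 0.0572). F8a and Ttc30a1 were among the genes with the largest falls, to mean signals of 11.7 and 16.6, near the pseudocount, so that their folds and order depend on it. The beta-actin 3'/5' ratio was 1.95 with both compounds and 1.25 without treatment, which bears on all of the gene groups given here.

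ATF4 genes rose in 18 of 26 cases with none down (adjusted over the list alone, 19; camera adjusted p = 4.04e-09, adjusted p = 0.0911 with an estimated correlation), including Ppp1r15a (12.9-fold), Atf3 (11.7-fold) and Ddit3 (9.65-fold). Immediate early genes rose in 18 of 26 cases and fell in 2 (adjusted over the list alone, 18 and 2; camera adjusted p = 4.04e-09, adjusted p = 0.16 with an estimated correlation). Cytokine genes rose in 13 of 30 and fell in 1 (adjusted over the list alone, 13 and 1; camera adjusted p = 7.41e-05, adjusted p = 0.0129 with an estimated correlation), with Ccl3 17.9-fold and Cxcl2 9.68-fold higher. Of 19 heat shock genes 11 rose and none fell (adjusted over the list alone, 12; camera adjusted p = 9.04e-05, adjusted p = 0.306 with an estimated correlation). Sterol synthesis genes rose in 11 of 19 cases with none down (adjusted over the list alone, 11; camera adjusted p = 0.000563, adjusted p = 0.241 with an estimated correlation). Hypoxia response genes rose in 13 of 18 with 1 down (adjusted over the list alone, 13 and 1; camera adjusted p = 0.000711, adjusted p = 0.333 with an estimated correlation), and glycolysis genes in 9 of 17 with 2 down (adjusted over the list alone, 12 and 2; camera adjusted p = 0.00102, adjusted p = 0.425 with an estimated correlation). Mitosis genes rose in 7 of 23 cases and fell in 1 (adjusted over the list alone, 7 and 1; camera adjusted p = 0.0962). In all, 1910 genes rose and 2381 fell, 586 and 615 of them at least 2-fold, whereas median centring gave 920 up and 3729 down and the values as deposited 92 up and 88 down. With the beta-actin ratio as a covariate 930 genes passed, with DPI + DNFB replicate 2 as the only array of its group 2113, and with the scaling target as a block 4541, against 2884 within the arrays scaled to 500 and 2622 within those scaled to 250.

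The interaction, the effect of DNFB with DPI minus its effect without DPI, tests whether the inhibitor changed the response to the allergen. Traf1 (log2 -5.44 ± 0.446 SE, n = 3 arrays a group, adjusted p = 4.04e-08), Cxcl3 (log2 -5.34 ± 0.442), Sgms2 (log2 -4.58 ± 0.822; -5.21 without non-treated replicate 2 and -3.91 without DPI + DNFB replicate 3) and Crisp3 (log2 -4.52 ± 0.3) had the most negative values, having risen with DNFB alone. Kcne3 (log2 4.23 ± 0.753), Tmem119 (log2 4.16 ± 0.262), Tifab (log2 3.83 ± 0.587) and Fut7 (log2 3.71 ± 0.57) had the most positive. Each had a lower mean signal with DPI alone than without treatment, and a higher one with both compounds than with DPI. For Tmem119 the mean signals were 2040 without treatment, 270.4 with DNFB, 523.3 with DPI and 1325 with both. These positive values thus rest in part on a lower signal on the DPI arrays than on the non-treated arrays. Mean signals of 19.9 for Sgms2 without treatment and 30.05 for Kcne3 with DNFB lay near the pseudocount of 15, so their interaction values depend on it. The NRF2 list was lower with DPI, with 15 of 25 genes negative and 2 positive (adjusted over the list alone, 15 and 5; shift -1.05, camera adjusted p = 2.24e-05, adjusted p = 0.00868 with an estimated correlation). The mitosis list was higher, with 20 of 23 genes positive and none negative (adjusted over the list alone, 22; shift 1.22, camera adjusted p = 8.34e-12, adjusted p = 0.011 with an estimated correlation). The DPI + DNFB arrays also had a higher beta-actin 3'/5' ratio, 1.95 against 1.28 on the DPI arrays, which bears on each of these differences.

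The p53 list had 8 of 19 genes negative and 2 positive (adjusted over the list alone, 8 and 2; camera adjusted p = 0.00153, adjusted p = 0.0265 with an estimated correlation). DNA replication genes were positive in 15 of 25 cases and negative in none (adjusted over the list alone, 17 and 1; camera adjusted p = 6.38e-05, adjusted p = 0.088 with an estimated correlation). Ribosome biogenesis genes were positive in 14 of 22 and negative in none (adjusted over the list alone, 15 and 1; camera adjusted p = 0.000194, adjusted p = 0.155 with an estimated correlation) and interferon response genes in 10 of 25 and none (adjusted over the list alone, 12; camera adjusted p = 0.00149, adjusted p = 0.563 with an estimated correlation). The cytokine list had 10 of 30 genes negative and 2 positive (adjusted over the list alone, 10 and 3; camera adjusted p = 0.0175, adjusted p = 0.0661 with an estimated correlation). The lysosome list had 9 of 25 negative and none positive (adjusted over the list alone, 9; camera adjusted p = 0.0049, adjusted p = 0.088 with an estimated correlation). Immediate early genes were negative in 8 of 26 cases and positive in 5 (adjusted over the list alone, 9 and 5; camera adjusted p = 0.0224, adjusted p = 0.561 with an estimated correlation). ER chaperones were negative in 5 of 20 and positive in 2 (adjusted over the list alone, 5 and 2; camera adjusted p = 0.0267, adjusted p = 0.561 with an estimated correlation). The calls of these last lists ended under 6 and 8 of 21 alternatives. The heat shock list was not called (camera adjusted p = 0.859), with 1 of 19 genes positive and 2 negative (adjusted over the list alone, 1 and 0).

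Over the 3105 genes that passed with DNFB alone, the median log2 fold change in the direction of that response was 0.731 without DPI and -0.143 with DPI, a ratio of -0.196. Over 22 alternatives the ratio lay between -0.204 and -0.111, and over the 15 fits that each left out 1 array between -0.209 and -0.171. The comparisons share no arrays, but choosing genes in the response to DNFB alone inflates the value there. Of these genes 38.7% kept their sign, 399 passed in the same direction with DPI (430.8 for independent lists) and 838 in the opposite direction (432.2 for independent lists). Chosen instead among the 3530 genes that passed with DPI, the medians were 0.668 with DPI and -0.123 without. Across all genes, which are not independent replicates, the fold changes with and without DPI correlated with r = -0.118. The interaction itself passed for 3945 genes, 2195 positive and 1750 negative. Median centring gave 1099 positive and 2410 negative and moved the median of all genes by -0.275, so this balance too depends on whether arrays are centred. The values as deposited gave 97 positive and 40 negative, but their unequal targets moved that median by 0.307. With the beta-actin ratio as a covariate 2577 genes passed, and with the scaling target as a block 4178, against 2265 within the arrays scaled to 500 and 2264 within those scaled to 250.

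**Figure D3:**
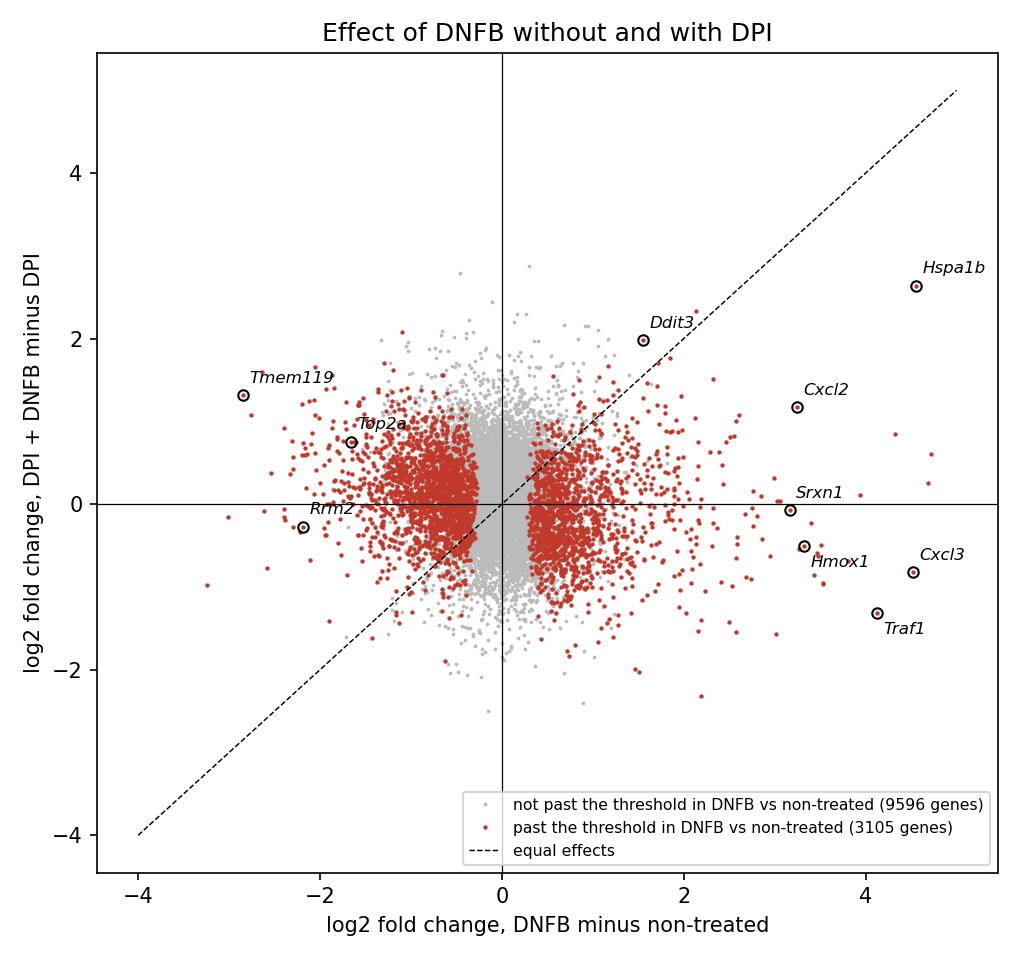
Log2 fold change of DNFB minus non-treated (horizontal axis) against DPI + DNFB minus DPI (vertical axis) for the 12701 tested genes, each a point, with the 3105 that passed in DNFB against no treatment in red and the dashed line marking equal effects. Srxn1, Hmox1, Cxcl3 and Traf1 lie far to the right and at or below 0 on the vertical axis, while Hspa1b and Cxcl2 lie above it at 2.64 and 1.17.

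**Figure D4:**
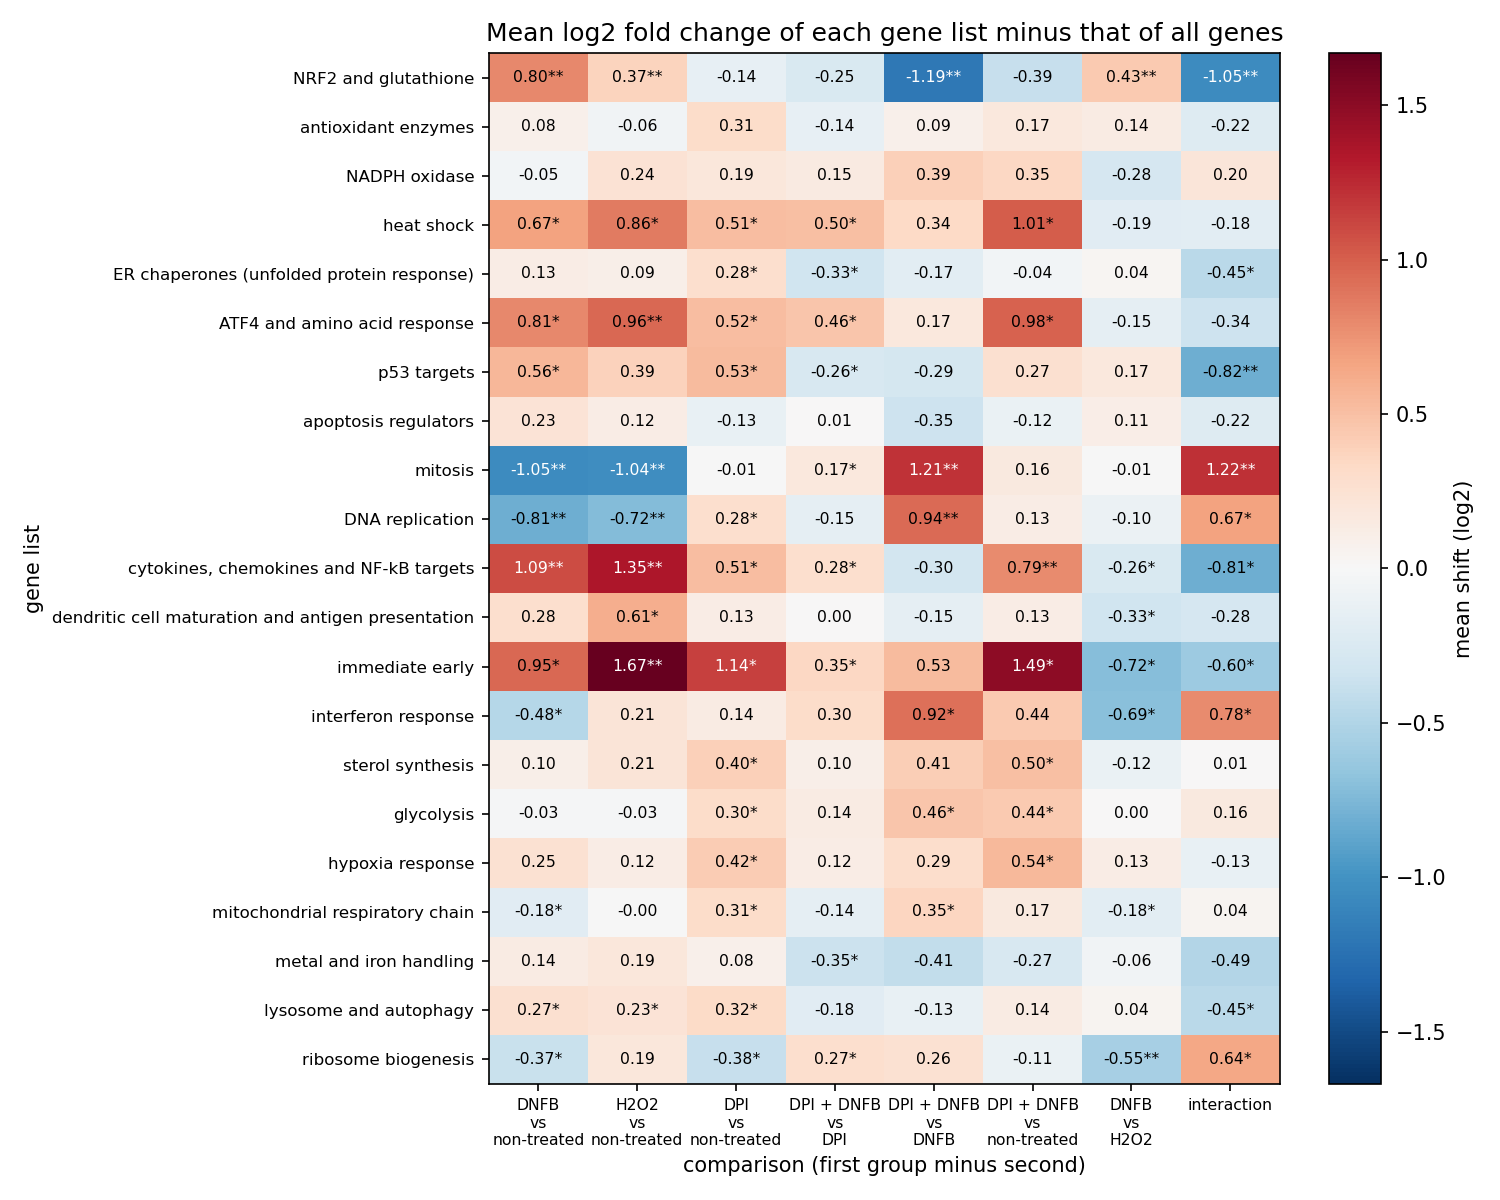
Mean log2 fold change of each gene list minus that of all genes, for the lists of pathways (vertical axis) and 8 comparisons (horizontal axis). An asterisk marks an adjusted camera p below 0.05 and a double asterisk one that also held with an estimated correlation; the mitosis list is at -1.05 with DNFB, -1.04 with H2O2 and -0.01 with DPI, each against no treatment.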

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

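All tests of explanations in this part were chosen after the results were seen; the counts of other splits of the arrays were planned. The response to DNFB differed with DPI in a test of the difference itself, which 3945 genes passed. Of 100 splits of the arrays 1, the real one, gave as many genes, and the highest of the others gave 2139. Such splits also mix the effects of DNFB and of DPI themselves. They therefore cannot exclude chance for the interaction by itself, nor a difference between single cultures. Of the lists that camera called for the interaction, NRF2 and glutathione (-1.054), p53 targets (-0.821) and cytokines (-0.814) had a negative mean shift. So did immediate early genes (-0.605), ER chaperones (-0.454) and lysosome (-0.45). Positive were mitosis (1.221), interferon response (0.784), DNA replication (0.665) and ribosome biogenesis (0.64). With an estimated correlation only the NRF2, p53 and mitosis calls held. The immediate early and ER chaperone calls ended under 6 and 8 of 21 alternatives.

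The genes with the most positive difference were Kcne3 (log2 4.226), Tmem119 (4.164), Tifab (3.829), Fut7 (3.708), Cbfa2t3 (3.426), Sun3 (3.406), Gna15 (3.36) and Lmnb2 (3.328). The most negative were Traf1 (-5.436), Cxcl3 (-5.34), Sgms2 (-4.584), Crisp3 (-4.516), Muc3 (-4.5), Procr (-4.498), Trib1 (-4.476) and Fam167a (-4.429). Some mean signals lay near the pseudocount of 15, so the size and order of such values depend on it. Examples are Kcne3 with DNFB (30.05), Sgms2 without treatment (19.9) and Fam167a with DPI (22.17). Each of the genes with the most positive difference had a lower mean signal with DPI alone than without treatment, as it had with DNFB alone. Control probe sets, which no comparison used, gave a 3'/5' ratio on the DPI + DNFB arrays of 1.954 for beta-actin and 1.104 for Gapdh, above the non-treated arrays at 1.248 and 0.849.

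For the 7 pairwise comparisons 10 splits of the arrays are too few for a share under 0.05, and the real split alone, 1 of the 10, gave as many genes in each. DNFB against no treatment gave 3105 genes and DNFB against H2O2 gave 1873, with 1 as the highest of the other splits. The other real values were 3591 for H2O2, 4035 for DPI and 4291 for DPI + DNFB, each against no treatment, 3530 for DPI + DNFB against DPI and 5617 against DNFB, all with 0 as the highest of the other splits.

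Mitosis genes fell with DNFB alone and not with DNFB in the presence of DPI, with an interaction of 1.221. With the scaling target as a block it was 1.198 (SE 0.095), which argues against the scaling batch as the whole cause. With the beta-actin ratio as a covariate it was 1.262 (SE 0.131), so a linear adjustment for the ratio did not lower it. The ratio largely follows the DPI + DNFB group, so that adjustment cannot exclude RNA quality. DPI alone left the list at -0.011 (SE 0.071), against -1.05 for DNFB alone, so a fall with DPI alone does not account for the pattern. RNA quality and unmeasured differences in culture or exposure remain open, the pattern stays a hypothesis, and cell division itself was not measured.

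Dim genes rose in DPI + DNFB relative to DPI, by a median of 0.214 (SE 0.085) in the dimmest of 3 equal parts of the tested genes. The 18015 probe sets under the signal filter rose by 0.192 (SE 0.056), and with the beta-actin ratio as a covariate the gap between the dimmest and the brightest part was 0.135 (SE 0.152), against 0.297 without it. A raised background, RNA quality and a biological change cannot be told apart here, since the ratio follows the DPI + DNFB group and the spread is wide. Earlier tests were replaced after their results were seen: with DPI + DNFB replicate 2 alone the gap between the medians was 0.157, against 0.245 with all arrays, and 1 array excludes nothing, while quantile and cyclic loess normalization gave -0.014 and -0.023 but remove such a gap by construction. No biological explanation was tested.

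Ribosome biogenesis genes were lower with DNFB than with H2O2, at a mean difference of -0.554. With the scaling target as a block the value was -0.536 (SE 0.083) and with quantile normalization -0.533 (SE 0.08), so neither the scaling batch nor the normalization accounts for it. A candidate explanation is a difference between allergen and oxidant, which stays a hypothesis because doses and times are not given.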

How the results depend on the processing

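The tests chosen only after the data were seen were the values as deposited, the scaling target as a block, the arrays of 1 scaling target, DPI + DNFB replicate 2 alone and the beta-actin covariate. Counts below follow the order DNFB, H2O2 and DPI against no treatment, DPI + DNFB against DPI, against DNFB and against no treatment, DNFB against H2O2, and interaction; unless a reason is given, the cause was not tested. Testing all probe sets, which tests more items, gave 4804, 5646, 6703, 6170, 10121 and 7920 for the first 6 and 6417 for the interaction. The values as deposited gave 210, 176, 214, 7, 829, 180, 26 and 137, with arrays of both targets in every group. A change of at least 2-fold left 879, 971, 1180, 668, 2083, 1201, 373 and 2016, and an adjusted p below 0.01 left 2050, 2391 and 2678, then 2111 against DPI, 2833 against no treatment, 924 and 2608, stricter by construction. The arrays scaled to 500, which are fewer, gave 1349 for DNFB, 2558 for DPI, 2225 against DPI, 3476 against DNFB, 353 against H2O2 and 2265 for the interaction. The arrays scaled to 250, with 1 array in most groups assumed to vary like the DNFB pair, gave 1784 for H2O2, 2326 for DPI, 1438 against DPI, 2622 against no treatment, 719 against H2O2 and 2264 for the interaction.

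DPI + DNFB replicate 2 alone, assumed to vary like the other groups, gave 1270, 3652 and 2113 for DPI + DNFB against DPI, DNFB and no treatment. Its beta-actin ratio lay within the range of the other groups but its Gapdh ratio, 0.952, did not, so it is not free of that difference. The beta-actin covariate gave 541, 2904 and 930 there and 2577 for the interaction; it largely follows that group, which widens the SE. The ratio of the DNFB effect with DPI to that without was -0.196, and moved to -0.118 with median centring, -0.156 with all probe sets, -0.162 with the mean of a gene's probe sets, -0.123 as deposited, -0.111 in the arrays scaled to 250, -0.153 with the covariate and -0.141 for changes of at least 2-fold. The overlap of DNFB and H2O2 was 84 as deposited, 865 and 1031 in the arrays scaled to 500 and 250, 454 at 2-fold and 1227 at the stricter threshold. List calls numbered 19 with an estimated correlation, 123 with fry, which tests another question, and 40 in the arrays scaled to 250, against 73.

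With each array left out in turn the counts ranged over 2502 to 3281, 2907 to 3785, 3264 to 4225, 2590 to 3794, 4902 to 5652, 3499 to 4465, 1251 to 2081 and 3483 to 4175, the ratio over -0.209 to -0.171, the overlap over 1511 to 2057 and the list calls over 63 to 76. With 1251 the lowest count for DNFB against H2O2 came without DNFB replicate 2. Of named genes, Slc11a2 with H2O2 (-0.101) and Ncf1 with DPI + DNFB (-0.124), each against no treatment, reversed with the mean of a gene's probe sets, and Hsp90aa1 between DNFB and H2O2 (0.004) with quantile normalization; none passed there. Of the 15 fits with 1 array left out, those that ended a list's call in DPI + DNFB against DPI numbered 11 for p53 targets, 10 for mitosis, 9 for metal and iron handling, 2 each for heat shock and ER chaperones and 1 each for cytokines, immediate early genes and ribosome biogenesis. In DPI against no treatment they numbered 4 for ER chaperones and 2 each for glycolysis and DNA replication, in DNFB against H2O2 3 for cytokines, and in the interaction 4 for ER chaperones and 2 for immediate early genes.

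Residuals of arrays with the same replicate number correlated with a mean r of 0.073 across genes, which are not independent replicates, and all 15 arrays correlated best with their own number, a hint of a shared batch that the labels do not state. With the replicate number as a block the counts were 3482, 3944, 4429, 3971, 5951, 4687, 2301 and 4334. The calls of 71 of 73 lists held with that block; the exceptions were mitosis and metal and iron handling in DPI + DNFB against DPI. The signal over background limits what dim genes can show, since those below the filter were not tested.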

Other observations

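The test of zinc finger genes and the matched sets in this part were chosen after the results were seen; the marker lists were planned. Camera called no marker list in any comparison. Among 8 measured macrophage and monocyte markers with DNFB, 2 rose and 3 fell (adjusted over the list alone, 2 and 3; camera adjusted p = 0.921, median below and mean above 0). Cd14, a coreceptor for bacterial lipopolysaccharide, rose 10.5-fold (log2 3.40 ± 0.138 SE, limma adjusted p = 1.29e-12) and 5.33-fold with H2O2, and was at a log2 fold change of -3.32 ± 0.138 in DPI + DNFB against DNFB. Csf1r, the receptor for macrophage colony-stimulating factor, fell by 1.26 with DNFB and by 1.44 with H2O2 on the log2 scale. Of 12 dendritic and Langerhans cell markers 2 rose with DNFB (adjusted over the list alone, 2; camera adjusted p = 0.594), among them Cd207 by 7.20-fold. Cd207 had a log2 fold change of 0.58 ± 0.435 with H2O2 (adjusted p = 0.359) and was 2.97-fold lower with DPI than without treatment, a call that ended without non-treated replicate 2.

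The other marker lists gave, with DNFB, camera adjusted p values of 0.875 for fibroblast, 0.594 for T cell and 0.376 for B cell. In DNFB against H2O2, 3 of 5 T cell markers were higher (adjusted over the list alone, 3; camera adjusted p = 0.186), Cd28 by 0.54 ± 0.134, Cd2 by 0.57 ± 0.175 and Zap70 by 1.78 ± 0.502 on the log2 scale. The calls of Cd2 and Zap70 ended when single arrays were left out, and 2 of the 3 probe sets of Zap70 had the opposite sign. There Cd14 was 1.98-fold and Cd207 4.81-fold higher. Keratinocyte, mast cell and melanocyte lists had too few measured members for the test. Of their 4, 3 and 4 measured members, Krt5 rose 3.31-fold and the adhesion gene Cdh1 was at a log2 fold change of -0.95 ± 0.29 with DNFB, and no other passed.

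DNFB and DPI, each against no treatment, shared 1122 genes in the same direction and had 373 in opposite directions, with 504.2 in the same direction for independent lists. The fold changes correlated across genes, which are not independent replicates, with r = 0.327. Simulations of unchanged groups gave 0.499, which shared controls alone produce. With many genes changed that value is no reference for the real r, and an r below it does not show unlike responses. Their covariance was 0.125 against a simulated 0.0492, a difference of 0.0758. Both comparisons use the same non-treated arrays, and how much of the overlap they account for was not tested.

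Genes with Zfp symbols, many of them coding for zinc finger proteins, are a set picked after the results were seen. Of 256 such genes 33.2% fell with DPI, against a mean of 18% in 10000 sets matched on mean signal, with a range of 13.7% to 22.7% for the central part of the sets. A set picked from these data would tend to exceed matched sets, so no p-value is given and no conclusion about low signal is drawn. In the other comparisons the shares that fell were 5.5% with DNFB and 9.8% with H2O2 against no treatment, with matched means of 12.4% and 17.2%. For DPI + DNFB they were 37.5% against no treatment, 18% against DPI and 39.8% against DNFB, with matched means of 15.4%, 9.7% and 17.2%, and for DNFB against H2O2 3.1%, with 4%. The pattern is a hypothesis, and no biological explanation was tested.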
